A study of Homo sapiens with 12 samples.

How the data were processed

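RNA of MDA-MB-231 cells was measured by RNA sequencing in 12 libraries, 3 in each of 4 groups defined by the glucose level and by cariporide. Total RNA was extracted with Trizol and made into stranded libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. The values used were the counts per gene deposited as 1 table for each library, for 40929 gene symbols. Per the submitters' processing notes, fastp, STAR, Salmon and GATK were used with the genome GRCh38, and which of these tools made the deposited counts is not given in the sources used here. Versions of those tools, and whether the counting used the strand, are not given in the sources used here either. The sequence reads were not used here.

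The library totals ran from 18069004 to 24837409 counts. CPM with TMM scaling and log2 fold changes were computed here from the counts. A gene was tested if it passed edgeR's filterByExpr with the 4 groups, which left 15104 genes. The test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to all 12 libraries with 1 mean for each group. The comparisons were CAR with NG, LG with NG, LGCAR with NG, LGCAR with LG and LGCAR with CAR. The interaction was the change with cariporide at 5 mM glucose minus that at 10 mM. P-values were adjusted for each comparison by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Nothing in the sources used here says that the libraries of a group came from separate cultures, so the p-values may measure technical spread. Groups of 3 were not tested for outliers.

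The comparisons, tests, thresholds, 31 gene lists with 711 entries and most alternatives were chosen before the data were examined. The lists covered transport, glucose and lipid metabolism, stress responses, mitochondria, cell cycle, signalling, cell state and markers of other cell types. Of their symbols 701 were in the tables, and 30 lists had at least 5 tested genes. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, then with an estimated correlation. Fry was used as well, which tests for a direction within a list and does not compare it with other genes. Members were also adjusted over the list alone. The median, mean and test direction of a list differed in sign in 24 of 180 cases, none of them called: 4 in CAR and 3 in LG against NG, 4 in LGCAR against NG, 6 in LGCAR against LG, 2 in LGCAR against CAR and 5 in the interaction.

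Genes were named by a rule fixed in advance. It took TXNIP, and up to 2 called members with the smallest p of each described list in the comparisons with NG. It also took the called genes with the highest and lowest log2 fold changes, 5 in each direction against NG and 3 elsewhere, that had a mean of at least 5 CPM in the higher group and no overlap of CPM between the groups. The last condition was not used for the interaction. Where no gene passed, the 3 with the smallest p were named. Results for some genes that the rule names are not reported here. Genes known by a locus number alone were left out of the named genes, and any gene outside the rule is said to be chosen after its value was seen. Calls of genes so chosen were not checked with a library left out or under the other settings in that comparison. Coordinates are those of RefSeq on GRCh38.p14, counted from 1, in which 14940 of the tested symbols (98.9%) were found and 164 were not. Exon overlap with other genes was taken from GENCODE 29, where all 60 named genes were found. Of these, 4 shared at least 10% of their exon length with another gene on the same strand and 3 on the opposite strand.

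Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, fits to the groups compared alone, replicate number as a block, a 2-fold limit and each library left out. After the data were seen 4 more were added: ribosomal RNA genes left out, the share of ribosomal RNA as a covariate, NG 1 and LGCAR 3 left out together, and a trend on GC content and length removed. Figures were made with matplotlib 3.10.9 in Python 3.11.15.

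The test was tested on simulated data with 15104 genes, of which 50 each were changed by 1.25, 1.5, 2 and 4-fold. At 1.5-fold it recovered 76% of the changed genes in CAR against NG, 70% in LG against NG, 56% in LGCAR against NG, 68% in LGCAR against LG, 58% in LGCAR against CAR and 56% in the interaction. At 1.25-fold the shares were 30%, 48%, 44%, 34%, 30% and 12% in the same order, at 2-fold 88%, 74%, 80%, 88%, 84% and 82%, and at 4-fold 98%, 96%, 94%, 90%, 96% and 92%. False calls made up 3.95%, 5.88%, 8.05%, 3.45%, 6.29% and 6.92% of the genes called. With simulated unchanged groups, 10 data sets gave the values of agreement that arise from shared controls. In all simulations each gene was drawn independently of the others. The shares of false calls and the values of agreement therefore leave out structure that the real libraries share across genes.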

Results

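RNA was sequenced from MDA-MB-231, an established human cell line of triple-negative breast cancer, after 48 h in medium with 10 or 5 mM glucose and with 0 or 25 µM cariporide. The 12 libraries formed 4 groups of 3, named NG (10 mM glucose), CAR (10 mM glucose with cariporide), LG (5 mM glucose) and LGCAR (5 mM glucose with cariporide). The total counts were 21583548, 20771898 and 23372248 for NG 1 to 3, 24837409, 22721107 and 23708870 for CAR 1 to 3, 23991233, 23030331 and 21093396 for LG 1 to 3, and 20464308, 18069004 and 19313786 for LGCAR 1 to 3. After the filter on low counts, 15104 genes were tested, and the common biological coefficient of variation was 6.94%.

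The share of ribosomal RNA varied between libraries and was not tested between the groups. Cytosolic ribosomal RNA held 9.48% ± 1.67 of the counts in NG, 7.87% ± 0.723 in CAR, 8.65% ± 0.649 in LG and 10.2% ± 1.12 in LGCAR (SD, n = 3 each), with the highest shares in NG 1 (11.2%) and LGCAR 3 (11.5%) and the lowest in CAR 1 (7.10%). Messenger RNA encoded in the mitochondrial genome held 5.87% ± 0.502 of the counts in NG, 6.26% ± 0.535 in CAR, 5.997% ± 0.589 in LG and 5.19% ± 0.283 in LGCAR (SD, n = 3 each). The share of cytosolic ribosomal RNA was at least 9.32% in LGCAR, and at most 8.53% in CAR and 9.06% in LG. With that share as a covariate, a change between LGCAR and CAR or LG can hardly be told apart from the share. Libraries of the same group differed by more than counting error, with a chi-square per degree of freedom of 2.82 to 24.6 over the 12 pairs.

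The comparison of LG with NG asked what lower glucose changed without cariporide. TXNIP, an arrestin-like inhibitor of glucose uptake whose transcription follows glucose supply, fell from 264 ± 12.5 CPM in NG to 46.4 ± 5.07 CPM in LG (SD, n = 3 each), which was 5.69-fold lower. ARRDC4, a related arrestin that also responds to glucose, fell from 5.94 ± 0.579 to 1.499 ± 0.357 CPM. TXNIP lies on chromosome 1 (GRCh38.p14, 145992435 to 145996579) and ARRDC4 on chromosome 15 (97960703 to 97973833). The log2 fold changes were -2.51 for TXNIP (SE 0.0775, edgeR adjusted p = 7.91e-12) and -1.98 for ARRDC4 (SE 0.175, edgeR adjusted p = 2.58e-05). KLF10, a zinc finger factor on chromosome 8 (102648784 to 102655725) chosen after its value was seen, fell with a log2 fold change of -0.49 (SE 0.0501, edgeR adjusted p = 9.27e-05). These 3 genes were the called members of the list of glucose-sensing targets of MondoA and ChREBP, and the other 7 members were not called. Over that list alone 4 genes fell, and the list had a median of -0.07 (camera adjusted p = 9.94e-06, and adjusted p = 0.0252 with an estimated correlation). Its median was -0.12 without NG 1 and -0.15 without LG 3.

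**Figure D1:**
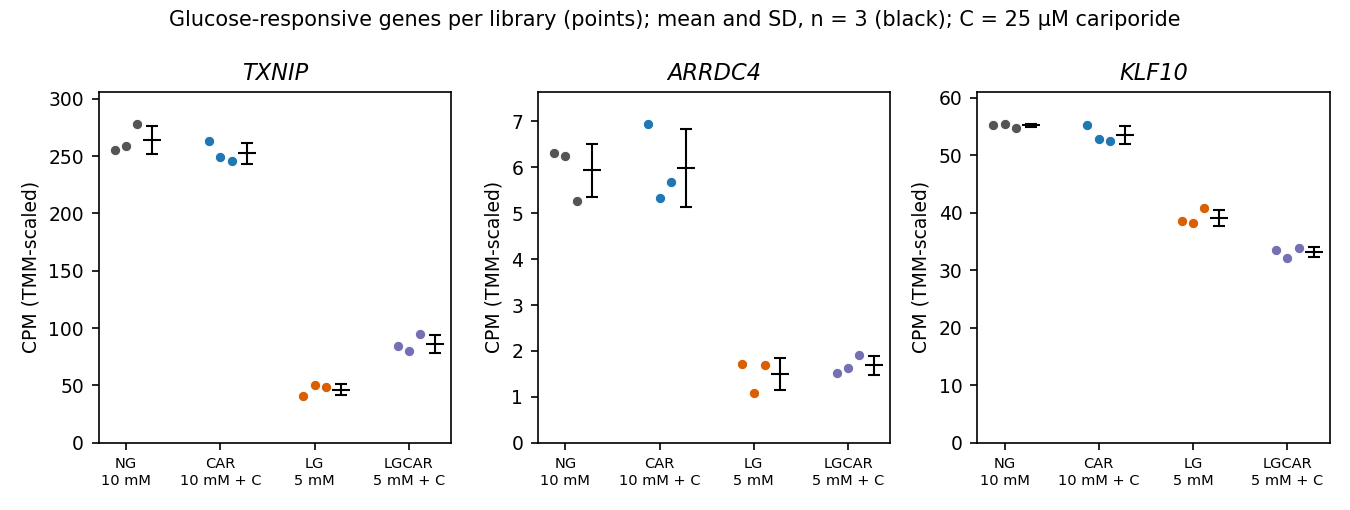
Normalised CPM (vertical axis) of TXNIP, ARRDC4 and KLF10 in each library (points) with the mean and SD of each group of 3 (black), for 10 mM glucose (NG), 10 mM glucose with 25 µM cariporide (CAR), 5 mM glucose (LG) and 5 mM glucose with cariporide (LGCAR). TXNIP was at 264 CPM in NG, 46.4 CPM in LG and 86.2 CPM in LGCAR, while ARRDC4 was at 5.94, 1.499 and 1.69 CPM and KLF10 at 55.1, 39.1 and 33.1 CPM.

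With these genes included, 261 of the 15104 tested genes differed between LG and NG by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 151 were higher and 110 lower in LG. Most changes were small, with a median size of 0.34 on the log2 scale and 6 genes past a 2-fold change. Among genes with a mean of at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a locus number, the largest rises were in 2 gel-forming mucins. MUC5B was at 2.54 ± 0.358 CPM in NG and 6.11 ± 0.503 CPM in LG (log2 fold change 1.27, SE 0.167, edgeR adjusted p = 0.00104). MUC5AC was at 7.15 ± 0.634 and 13.8 ± 1.96 CPM (0.95, SE 0.145, edgeR adjusted p = 0.00422). GRAMD1B, a sterol carrier, rose by 0.80 on the log2 scale, ID3, an inhibitor of helix-loop-helix factors, by 0.73, and DBP, a clock-controlled transcription factor, by 0.73. FOS, an immediate-early transcription factor, fell from 17.0 ± 1.999 to 9.43 ± 0.571 CPM (log2 fold change -0.85, SE 0.106, edgeR adjusted p = 5.82e-04), TCAF2 changed by -0.68 and BHLHA15, a factor of secretory cells, by -0.60. DBP shared 10.1% of its exon length with a gene on the opposite strand. The calls of GRAMD1B (without NG 1, NG 3, LG 1 or LG 2) and DBP (without any 1 of the 6 libraries) were lost when 1 library was left out, with edgeR adjusted p of 0.0542 to 0.106 and 0.0503 to 0.172. The number of genes called was 167 without NG 1, 98 without NG 2, 83 without NG 3, 88 without LG 1 and 99 without LG 2. With library totals as the only scaling, 69.5% of the called genes were higher in LG, against 57.9% with the main scaling.

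Chaperone genes were lower in LG. Of 15 tested heat shock genes 6 fell, 9 were not called and none rose, and 10 fell when adjusted over the list alone. HSPA8, a constitutive chaperone, had a log2 fold change of -0.36 (SE 0.0598, edgeR adjusted p = 0.00516) and HSPA1B, an inducible one, -0.28 (SE 0.0447, edgeR adjusted p = 0.00454). HSPA1B is nearly identical to HSPA1A and shared 36.5% of its exon length with another gene on the same strand, so its counts are uncertain. The list had a median of -0.20 (camera adjusted p = 2.13e-10, and adjusted p = 0.0300 with an estimated correlation). Of 21 genes of the unfolded protein response 3 fell, HYOU1 and DNAJB9 with a log2 fold change of -0.24 each and HSPA5, chosen after its value was seen, with -0.22, and 6 fell when adjusted over the list alone. Its median was -0.09 (camera adjusted p = 1.29e-05, but adjusted p = 0.0522 with an estimated correlation). Among 32 targets of ATF4, the factor of the integrated stress response, 5 fell and 1 rose, with 10 and 2 adjusted over the list alone. SLC3A2, a subunit of amino acid transporters, and PSAT1, an enzyme of serine synthesis, each changed by -0.31, while DDIT3, a factor of the same response chosen after its value was seen, rose by 0.29. The median of the ATF4 list was -0.11 (camera adjusted p = 1.29e-05, but adjusted p = 0.232 with an estimated correlation), and -0.18 without LG 3. DNAJB9 lost its call without NG 1, NG 2, NG 3, LG 1 or LG 2 (edgeR adjusted p = 0.0596 to 0.129) and PSAT1 without NG 3, LG 1 or LG 2 (edgeR adjusted p = 0.0636 to 0.0737). HYOU1 lost its call without NG 1 and LGCAR 3 together (edgeR adjusted p = 0.0631). Calls of HSPA5 and DDIT3 were not checked in these ways.

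Genes of DNA replication, hypoxia and ribosome biogenesis were lower in LG as well. Of 29 genes of DNA replication and the G1/S transition 5 fell, and 8 adjusted over the list alone, among them FEN1, a flap endonuclease, by -0.28 and CDC6, a licensing factor, by -0.29 (camera adjusted p = 2.66e-08, and adjusted p = 0.0300 with an estimated correlation). The mitosis list had no called member among 26 and a median of 0.03, with a camera adjusted p of 0.240 that was 0.0418 without NG 3. Of 26 hypoxia genes 4 fell, and 11 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 5.46e-08, and adjusted p = 0.0300 with an estimated correlation). VEGFA, an angiogenic factor chosen after its value was seen, changed by -0.24. Of 25 MYC targets and ribosome biogenesis genes 2 fell, NOP56 with -0.26 and NOLC1 with -0.18, and 5 fell adjusted over the list alone (camera adjusted p = 3.52e-07, and adjusted p = 0.0252 with an estimated correlation). The median of that list was -0.09, and -0.14 without LG 3. Calls were lost for CDC6 without NG 2, NG 3, LG 1 or LG 2 (edgeR adjusted p = 0.0522 to 0.0813), for NOP56 without the same libraries (0.129 to 0.230) and for NOLC1 without NG 1, NG 2, NG 3, LG 1 or LG 2 (0.101 to 0.214).

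Metabolic and transport genes gave a mixed picture in LG. Of 24 genes of glucose uptake and glycolysis 2 fell, the regulatory kinases PFKFB4 by -0.41 (SE 0.0707, edgeR adjusted p = 0.00647) and PFKFB3 by -0.29 (SE 0.0529, edgeR adjusted p = 0.0106), and 6 fell adjusted over the list alone. The glycolysis list had a median of -0.03 (camera adjusted p = 0.0115, but adjusted p = 0.290 with an estimated correlation), which was -0.07 without NG 1 and -0.06 without LG 3. Of 29 genes of acid-base and ion transport 1 rose and 1 fell, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.551). CA12, a carbonic anhydrase of the cell surface, rose by 0.54, and SLC16A3, a lactate exporter, fell by 0.22 on the log2 scale. None of 25 genes of cholesterol synthesis was called (camera adjusted p = 0.970). SLC16A3 lost its call without any 1 of the 6 libraries (edgeR adjusted p = 0.0569 to 0.184), and PFKFB3 without LG 2 (edgeR adjusted p = 0.0646).

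Other lists moved upward in LG. Of 23 NF-kB target genes 3 rose, and 7 adjusted over the list alone, among them CXCL2, a chemokine, by 0.61 and TNFAIP3, a feedback inhibitor of NF-kB, by 0.58. The NF-kB list had a median of 0.14 (camera adjusted p = 7.02e-04, but adjusted p = 0.472 with an estimated correlation), and 0.07 without LG 3, where its call was lost (camera adjusted p = 0.161). Of 17 YAP and TEAD targets 2 rose, NUAK2 by 0.53 and LATS2 by 0.26, and 7 rose adjusted over the list alone (median 0.16, camera adjusted p = 8.25e-05, but adjusted p = 0.0618 with an estimated correlation). Of 32 genes of autophagy and the lysosome 4 rose, among them NPC1, a cholesterol exporter of the lysosome, by 0.29 and CTSD, a lysosomal protease, by 0.35, and 8 rose and 2 fell adjusted over the list alone. The lysosome list had a median of 0.05 (camera adjusted p = 0.0345, but adjusted p = 0.355 with an estimated correlation), and its call was lost without NG 1 (median 0.03, camera adjusted p = 0.172), NG 2 (0.0525) or LG 3 (median 0.01, 0.290). It also ended with the share of ribosomal RNA as a covariate (median 0.03, camera adjusted p = 0.222) and without NG 1 and LGCAR 3 together (0.206). CTSD shared 41.7% of its exon length with another gene on the same strand and 15.8% with one on the opposite strand, so its value is uncertain. Its call ended without NG 1 and LGCAR 3 together (edgeR adjusted p = 0.0514). Among 5 basal and myoepithelial markers OXTR, the oxytocin receptor, rose by 0.55 and MYLK, a myosin kinase, by 0.33, which was also the count adjusted over the list alone (median 0.33, camera adjusted p = 0.0221, but adjusted p = 0.106 with an estimated correlation). NUAK2 lost its call without NG 3 or LG 1 (edgeR adjusted p = 0.0800 to 0.0835), with log2 fold changes of 0.49 and 0.43. LATS2 lost it without NG 2, NG 3, LG 1 or LG 2 (0.121 to 0.169), with 0.22 to 0.26. The call of OXTR was lost without NG 2, NG 3 or LG 1 (edgeR adjusted p = 0.0703 to 0.0843), with 0.46 to 0.50. That of MYLK was lost without NG 2, NG 3, LG 1 or LG 2 (0.156 to 0.197), with 0.26 to 0.32.

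Histone and ribosomal protein transcripts shifted in LG without called members. The 13 tested histone genes, many with near-identical copies and therefore uncertain, had a median of -0.21 (camera adjusted p = 0.00307, but adjusted p = 0.355 with an estimated correlation), which was -0.11 without NG 2 and -0.10 without LG 1. The 30 ribosomal protein genes had a median of -0.05 (camera adjusted p = 0.0472, but adjusted p = 0.824 with an estimated correlation), beside a share of cytosolic ribosomal RNA of 9.48% in NG and 8.65% in LG. That ribosomal protein call was lost without NG 2 (camera adjusted p = 0.0573), NG 3 (median -0.01, 0.821), LG 1 (-0.01, 0.697) or LG 2 (-0.03, 0.341), and the median was -0.10 without NG 1 and -0.12 without LG 3. Both calls ended over genes with a mean of at least 5 CPM, at camera adjusted p = 0.0590 for histones and 0.0690 for ribosomal proteins. No member of either list passed over the list alone.

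The comparison of LGCAR with NG asked what lower glucose and cariporide changed together. ARRDC4 fell to 1.69 ± 0.203 CPM (log2 fold change -1.81, SE 0.177, edgeR adjusted p = 4.62e-05) and TXNIP to 86.2 ± 7.55 CPM (n = 3 each), which was 3.06-fold lower than in NG (log2 fold change -1.61, SE 0.0745, edgeR adjusted p = 4.32e-09). FOS fell to 6.34 ± 0.391 CPM (log2 fold change -1.42, SE 0.114, edgeR adjusted p = 4.38e-06). Its relative FOSB fell from 6.41 ± 1.61 to 2.97 ± 0.811 CPM (-1.11, SE 0.189, edgeR adjusted p = 0.00514) and KLF10 from 55.1 ± 0.324 to 33.1 ± 0.888 CPM (-0.73, SE 0.0513, edgeR adjusted p = 7.65e-07). The read-through transcript TIMM23B-AGAP6 changed by -0.76 but shared 18.4% of its exon length with another gene on the same strand and 10.4% with one on the opposite strand, so its value is uncertain. Under the same limits on level, overlap and symbol, the largest rises were ATP8A1, a phospholipid flippase, by 0.90 on the log2 scale, OLFML2A, an extracellular matrix protein, by 0.89, MUC5AC by 0.88, PIK3C2B, a lipid kinase, by 0.77 and DBP by 0.70.

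Together, 1322 of 15104 genes differed between LGCAR and NG by edgeR's test with Benjamini-Hochberg adjustment, 700 higher and 622 lower, with a median size of 0.30 on the log2 scale and 31 genes past a 2-fold change. Of the called genes 52.95% were higher. The share was 45.8% with RLE size factors, 46.4% without ribosomal RNA genes and 41.2% without a filter. It was 45.2% with a trend on GC content and length removed and 48.8% by DESeq2. The number called was 293 without NG 2, 136 without NG 3, 197 without LGCAR 1, 324 without LGCAR 2 and 335 without LGCAR 3. Among the genes named above, calls were lost for OLFML2A without NG 2, NG 3, LGCAR 1 or LGCAR 3 (edgeR adjusted p = 0.0559 to 0.102), PIK3C2B without NG 3 (0.0587), and DBP without NG 2, NG 3, LGCAR 1 or LGCAR 3 (0.0605 to 0.123). FOSB had a log2 fold change of -0.70 without NG 1 and LGCAR 3 together. TIMM23B-AGAP6 lost its call without any 1 of the 6 libraries (edgeR adjusted p = 0.0734 to 0.167). MUC5AC and CA12 narrowly lost theirs when a trend on GC content and length was removed (edgeR adjusted p = 0.0536 and 0.0565).

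Stress-response genes were lower in LGCAR. Of 32 ATF4 targets 20 fell and none rose, and 24 fell adjusted over the list alone, with a median of -0.25 (camera adjusted p = 5.24e-11, but adjusted p = 0.0664 with an estimated correlation). SLC3A2 went from 319 ± 10.8 to 229 ± 2.70 CPM (log2 fold change -0.48, SE 0.0519, edgeR adjusted p = 1.82e-04) and ASNS, asparagine synthetase, from 128 ± 4.38 to 101 ± 0.522 CPM (-0.35, SE 0.0478, edgeR adjusted p = 0.00158). ASNS shared 44.6% of its exon length with another gene on the same strand, so its value is uncertain. ATF4 itself, chosen after its value was seen, fell by 0.40 on the log2 scale (edgeR adjusted p = 0.00514). Of 21 genes of the unfolded protein response 12 fell and none rose, and 13 fell adjusted over the list alone, with a median of -0.19 (camera adjusted p = 2.12e-07, and adjusted p = 0.0334 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 4746 ± 208 to 3701 ± 26.5 CPM (log2 fold change -0.36, SE 0.0517, edgeR adjusted p = 0.00180) and HYOU1, another of its chaperones, changed by -0.30. Of 15 heat shock genes 8 fell and all 15 fell adjusted over the list alone, with a median of -0.28 (camera adjusted p = 1.09e-10, and adjusted p = 0.0334 with an estimated correlation). HSPA1B and HSPA1A, which are near-identical and uncertain for that reason, had log2 fold changes of -0.34 and -0.36.

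Growth-related lists were lower in LGCAR too. Of 25 MYC targets 10 fell, and 16 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 1.45e-07, and adjusted p = 0.0334 with an estimated correlation). ODC1, the enzyme that starts polyamine synthesis, changed by -0.32 and NOP56, a nucleolar protein, by -0.36. All 30 ribosomal protein genes had a log2 fold change under 0, of which 3 fell and 28 fell adjusted over the list alone, RPL10A by -0.25 and RPL27 by -0.22 among them. The ribosomal protein median was -0.20 (camera adjusted p = 1.39e-09, but adjusted p = 0.461 with an estimated correlation), beside a share of cytosolic ribosomal RNA of 9.48% in NG and 10.2% in LGCAR. Of 29 genes of DNA replication 4 fell, also over the list alone, among them CDC6 by -0.24 and CCNE1, a cyclin of G1/S, by -0.39 (median -0.08, camera adjusted p = 0.0129, but adjusted p = 0.341 with an estimated correlation). No mitosis gene was called among 26 (median 0.02, camera adjusted p = 0.910). Calls were lost with 1 library left out for CDC6 (NG 2, NG 3, LGCAR 1 or LGCAR 2, edgeR adjusted p = 0.0530 to 0.105) and, without NG 2, NG 3 or any 1 of the LGCAR libraries, for CCNE1 (0.0564 to 0.118), RPL10A (0.0701 to 0.144) and RPL27 (0.0908 to 0.196). With a trend on GC content and length removed, the log2 fold changes were -0.10 for RPL10A and -0.12 for RPL27.

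Glucose-sensing, hypoxia and mitochondrial lists were lower in LGCAR. The glucose-sensing list had 3 called members among 10, TXNIP, ARRDC4 and KLF10, and 4 adjusted over the list alone, all lower (median -0.12, camera adjusted p = 2.46e-04, and adjusted p = 0.0334 with an estimated correlation). Of 24 genes of glucose uptake and glycolysis 2 rose and 3 fell, with 2 and 9 adjusted over the list alone (median -0.06, camera adjusted p = 0.110, and 0.0485 without NG 1). SLC2A1, the main glucose transporter, changed by -0.19 and PFKFB2, a regulatory kinase, by 0.38. Of 26 hypoxia genes 7 fell, and 11 fell and 1 rose adjusted over the list alone, with a median of -0.13 (camera adjusted p = 1.83e-06, but adjusted p = 0.0613 with an estimated correlation). Within it VEGFA, an angiogenic factor, changed by -0.37 (SE 0.0573, edgeR adjusted p = 0.00258). Of 31 nuclear genes of oxidative phosphorylation 2 fell, also over the list alone, CYCS by -0.35 and ATP5MC1 by -0.27 (median -0.11, camera adjusted p = 0.00110, but adjusted p = 0.584 with an estimated correlation). Of 13 transcripts of the mitochondrial genome 1 fell, CYTB by -0.28, and 2 adjusted over the list alone (median -0.18, camera adjusted p = 0.0166, but adjusted p = 0.603 with an estimated correlation), beside a share of mitochondrial messenger RNA of 5.87% in NG and 5.19% in LGCAR. The oxidative phosphorylation call was lost without NG 3 (median -0.05, camera adjusted p = 0.0513), with a median of -0.17 without NG 1, and the mitochondrial call without NG 3 (median -0.12, 0.120) or LGCAR 3 (0.104). With the share of ribosomal RNA as a covariate the mitochondrial median was -0.09 and its call ended (camera adjusted p = 0.0567). SLC2A1, PFKFB2, ATP5MC1 and CYTB lost their calls without NG 2, NG 3 or any 1 of the LGCAR libraries (edgeR adjusted p = 0.0678 to 0.117, 0.0829 to 0.162, 0.0775 to 0.169 and 0.0783 to 0.153). With a trend on GC content and length removed PFKFB2 had a log2 fold change of 0.23 and VEGFA of -0.61.

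Transport, sterol and YAP lists held few changes in LGCAR. Of 29 genes of acid-base and ion transport 2 rose, among them CA12 by 0.48 (SE 0.0874, edgeR adjusted p = 0.00661), and 5 rose and 2 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.261). Of 25 genes of cholesterol synthesis LSS, a cyclase of that pathway, rose by 0.17, and it was also the call adjusted over the list alone (median 0.01, camera adjusted p = 0.784). Of 17 YAP and TEAD targets LATS2 rose by 0.25 and CRIM1 by 0.28, and 6 rose and 1 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.0375, but adjusted p = 0.350 with an estimated correlation). The YAP call was lost without NG 3 (camera adjusted p = 0.0809) or LGCAR 1 (0.0817). LSS lost its call (edgeR adjusted p = 0.0512 to 0.140) without any 1 of the 6 libraries. LATS2 lost its call without NG 2, NG 3, LGCAR 1 or LGCAR 3 (edgeR adjusted p = 0.0848 to 0.116) and CRIM1 without NG 2, NG 3 or any 1 of the LGCAR libraries (0.0697 to 0.151). With a trend on GC content and length removed, their log2 fold changes were 0.16 and 0.17.

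**Figure D2:**
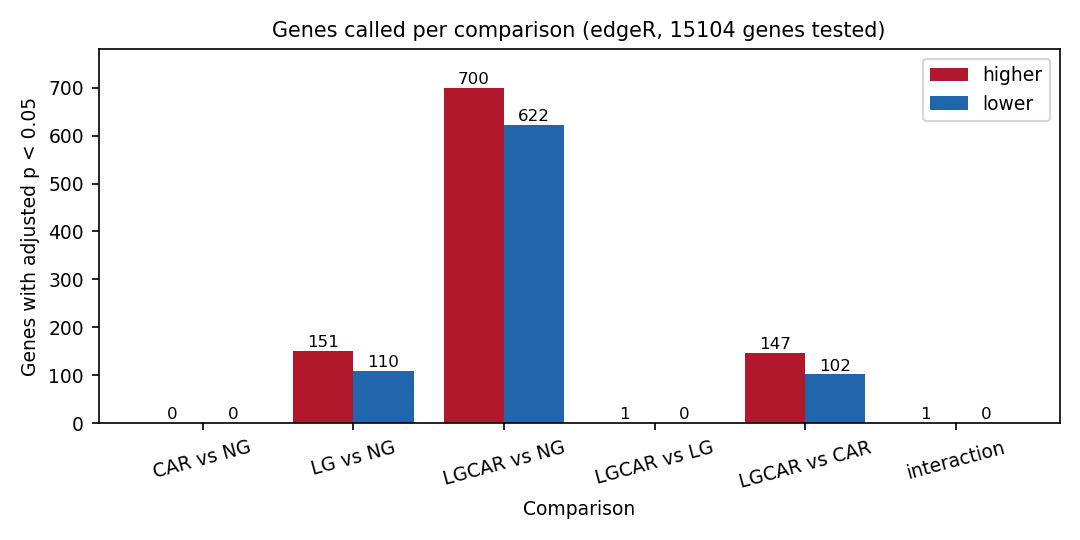
Number of genes higher (red) and lower (blue) at a Benjamini-Hochberg adjusted p under 0.05 by edgeR in each comparison of the 4 groups of 3 libraries and in the interaction of glucose and cariporide. LGCAR against NG gave 700 higher and 622 lower genes, LG against NG 151 and 110, and CAR against NG none.

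The comparison of CAR with NG asked what cariporide changed at 10 mM glucose. TXNIP was at 264 ± 12.5 CPM in NG and 253 ± 9.33 CPM in CAR (log2 fold change -0.06, SE 0.0713, and -0.10 to -0.02 over the other settings), n = 3 each, and it did not pass edgeR's test. No gene passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 684 of 15104 at an unadjusted p under 0.05, where chance alone would give 755.2. DESeq2 called 1 gene (475 unadjusted) and limma-voom 0 (711 unadjusted). With the share of ribosomal RNA as a covariate edgeR called 0 genes, with 2696 at an unadjusted p under 0.05. The gene called by DESeq2, chosen after its value was seen, was the histone gene H2AC19, which lay at 9.02 CPM in CAR 2, 7.21 CPM in CAR 3, 8.35 CPM in LG 2 and 0 in the other 9 libraries, and which has a near-identical copy that makes its counts uncertain. The smallest p belonged to H2BC18, another histone gene (log2 fold change -0.58), RNR1, a mitochondrial ribosomal RNA (-0.37, and -0.22 with the share of ribosomal RNA as a covariate), and LINC01355, a long non-coding RNA (0.66), each with an edgeR adjusted p of 0.894. With NG 1 and CAR 1 exchanged between the groups, a split singled out after its count was seen, edgeR called 846 genes, and the labels were kept as given. For 79.7% of the genes tested, the 95% interval of the fold change lay within 1.5-fold in either direction. The number called by edgeR was 2 without NG 1, 1 without NG 2 and 1 without NG 3, and the unadjusted count was 2574 without CAR 1, 416 without CAR 2 and 406 without CAR 3.

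Gene lists shifted slightly between CAR and NG, and none of their members was called by edgeR over all genes. The medians were -0.07 for 32 ATF4 targets (camera adjusted p = 6.91e-04), -0.05 for 21 genes of the unfolded protein response (0.00576), -0.09 for 15 heat shock genes (2.28e-05), and -0.07 for 25 MYC targets (6.91e-04). They were -0.08 for 30 ribosomal protein genes (camera adjusted p = 1.15e-04), -0.05 for 31 nuclear genes of oxidative phosphorylation (0.0179), -0.10 for 11 luminal epithelial markers (0.0151), -0.23 for 13 histone genes (2.28e-05) and 0.07 for 13 mitochondrially encoded transcripts (0.0179). With an estimated correlation none of these 9 was called, at camera adjusted p = 0.603, 0.374, 0.355, 0.340, 0.739, 0.739, 0.603, 0.374 and 0.739 in the same order. Adjusted over the list alone, 4 histone genes and 1 gene of the unfolded protein response fell, and 1 mitochondrially encoded transcript rose. The share of mitochondrial messenger RNA was 5.87% in NG and 6.26% in CAR, and that of cytosolic ribosomal RNA 9.48% and 7.87%. The acid-base (median 0.01), glycolysis (-0.02), glucose-sensing (-0.05), cholesterol (-0.02), DNA replication (-0.02) and mitosis (-0.01) lists were not called, at camera adjusted p of 0.924, 0.576, 0.576, 0.112, 0.492 and 0.537, nor was any of their members over the list alone.

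Part of the list calls in CAR against NG depended on which libraries were used. The mitochondrial median was -0.01 without CAR 1 (camera adjusted p = 0.746) and 0.03 without NG 1 (0.625), its call was lost without NG 2 (0.0513), and it was 0.13 without NG 3 and 0.11 without CAR 2. The ribosomal protein call was lost without NG 3 (median -0.03, camera adjusted p = 0.208), CAR 2 (-0.04, 0.0646) or CAR 3 (-0.04, 0.0543), and its median was -0.12 without NG 1 and -0.16 without CAR 1. The oxidative phosphorylation call was lost without NG 2 (0.0519), NG 3 (median -0.01, 0.909), CAR 2 (-0.03, 0.386) or CAR 3 (-0.02, 0.256), with a median of -0.09 without NG 1 or CAR 1. The luminal call was lost without NG 2 (0.0922), CAR 2 (0.0646) or CAR 3 (0.1003), with a median of -0.17 without CAR 1. The median of the MYC list was -0.04 without NG 3 or CAR 2, and that of the unfolded protein response -0.09 without CAR 1. Without CAR 1 the cholesterol (median -0.08, camera adjusted p = 0.00154), hypoxia (-0.06, 0.0289) and NF-kB (-0.08, 0.0140) lists were called, and the NF-kB list also without NG 2 (0.0405). With the share of ribosomal RNA as a covariate the mitochondrial median turned to -0.07 without a call (camera adjusted p = 0.0890) and the histone call ended (median -0.15, camera adjusted p = 0.0548). Without NG 1 and LGCAR 3 together the mitochondrial call ended (median 0.03, camera adjusted p = 0.611).

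The comparison of LGCAR with LG asked what cariporide changed at 5 mM glucose. TXNIP rose from 46.4 ± 5.07 CPM in LG to 86.2 ± 7.55 CPM in LGCAR (SD, n = 3 each), 1.86-fold, with a log2 fold change of 0.90 (SE 0.0766, edgeR adjusted p = 4.60e-05). It was the 1 gene called by edgeR with Benjamini-Hochberg adjustment, with 1801 of 15104 genes at an unadjusted p under 0.05, and it stayed far below its level of 264 CPM in NG. ARRDC4, chosen after its value was seen, was at 1.499 ± 0.357 and 1.69 ± 0.203 CPM and had a log2 fold change of 0.17 (95% interval up to 0.62) that did not pass. DESeq2 called 20 genes, chosen here after their values were seen, among them the stress genes PPP1R15A (log2 fold change -0.38) and GDF15 (-0.56), the chemokines CXCL1 (-0.51) and CXCL2 (-0.44), the NF-kB inhibitor TNFAIP3 (-0.41), and the growth-response genes MYC (-0.30), EGR1 (-0.89), DUSP1 (-0.38) and FOS (-0.57). Of the 20 genes 15 fell and 5 rose, the latter being TXNIP and genes known by a locus number alone. The 20 included H2AC19 (-22.6), above 0 only in LG 2 of these libraries, and a locus with a value of 23.7. Values of that size are not usable folds. The number called by edgeR was 3 without LG 2 and 2 without LGCAR 3.

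Lists of inflammatory and stress genes were lower in LGCAR than in LG as groups. Of 23 NF-kB targets 22 had a log2 fold change under 0 and none was called by edgeR over all genes, while 17 fell adjusted over the list alone, with a median of -0.26 (camera adjusted p = 1.08e-11, but adjusted p = 0.307 with an estimated correlation). Immediate-early genes had a median of -0.13, with 11 of 22 falling and 1 rising adjusted over the list alone (camera adjusted p = 1.73e-05, but adjusted p = 0.307 with an estimated correlation). ATF4 targets had a median of -0.13, with 12 of 32 falling adjusted over the list alone (camera adjusted p = 1.86e-07, but adjusted p = 0.307 with an estimated correlation). The unfolded protein response had -0.09, with 1 of 21 falling adjusted over the list alone (camera adjusted p = 9.53e-04, but adjusted p = 0.307 with an estimated correlation). Without LG 3 the NF-kB median was -0.17 and the immediate-early median -0.08, and both stayed called. Fry called these 4 lists too, at adjusted p of 0.0361, 0.0361, 0.0361 and 0.0304 in the order given.

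Ribosomal, mitochondrial and other lists were also called between LGCAR and LG, with no member called by edgeR over all genes or over the list alone. The median was -0.15 for 30 ribosomal protein genes (camera adjusted p = 1.41e-09, but adjusted p = 0.496 with an estimated correlation) and -0.19 for 13 mitochondrially encoded transcripts (5.24e-04, but adjusted p = 0.523 with an estimated correlation). Cytosolic ribosomal RNA held 8.65% of the counts in LG and 10.2% in LGCAR, and mitochondrial messenger RNA 5.997% and 5.19%. Nuclear genes of oxidative phosphorylation had -0.07 (camera adjusted p = 0.00288), DNA replication 0.06 (0.00565), heat shock -0.06 (0.0254), MYC targets -0.06 (0.0317), the lysosome -0.05 (0.0317) and luminal markers -0.10 (0.0462), and with an estimated correlation the adjusted p were 0.589, 0.324, 0.496, 0.324, 0.493 and 0.496 in that order. Acid-base (median 0.03, camera adjusted p = 0.458), glycolysis (-0.01, 0.498), cholesterol (0.01, 0.587) and mitosis (-0.03, 0.336) lists were not called and held no member past the list alone, and the glucose-sensing list (-0.01, 0.794) had TXNIP rising and 1 member falling adjusted over the list alone. Without LG 3 the ribosomal protein median was -0.10, the mitochondrial -0.11 and that of oxidative phosphorylation -0.04, where its call was lost (0.188), while it was -0.12 without LG 1. The DNA replication call was lost without LG 1 (0.0547) or LGCAR 3 (median 0.03, 0.163), with a median of 0.03 without LG 2, the lysosome call without LG 3 (0.110) or LGCAR 3 (0.0974), and the heat shock call without LG 2 (0.0648). Calls of MYC targets were lost without LG 1 (0.0524), LG 2 (0.0554), LGCAR 1 (0.0513) or LGCAR 2 (0.120), and of luminal markers without LG 1 (0.0524), LG 2 (0.0554), LG 3 (0.117), LGCAR 1 (0.134) or LGCAR 2 (0.108). As a covariate, the share of ribosomal RNA ended 6 calls: oxidative phosphorylation (median -0.01, camera adjusted p = 0.980), mitochondrial transcripts (-0.05, 0.722), lysosome (-0.01, 0.453), heat shock (-0.04, 0.224), luminal markers (-0.07, 0.161) and MYC targets (-0.04, 0.0512). The shares of LG and LGCAR did not overlap, so the fit with the covariate may also take out the change between the groups. Over genes with a mean of at least 5 CPM the lysosome and MYC calls ended, each at a camera adjusted p of 0.0644. Without NG 1 and LGCAR 3 together those of DNA replication (0.185), the lysosome (0.110) and heat shock (0.0519) ended.

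The comparison of LGCAR with CAR asked what lower glucose changed in the presence of cariporide. ARRDC4 fell with a log2 fold change of -1.83 (SE 0.176, edgeR adjusted p = 4.48e-05), TXNIP with -1.55 (SE 0.0744, edgeR adjusted p = 7.80e-09), from 253 ± 9.33 to 86.2 ± 7.55 CPM (n = 3 each), and FOS with -1.17 (SE 0.115, edgeR adjusted p = 4.68e-05). KLF10, the remaining called member of the glucose-sensing list, was chosen after its value was seen and changed by -0.69 (SE 0.0511). MUC5AC rose by 0.93 (SE 0.146, edgeR adjusted p = 0.00526), DBP by 0.85 (SE 0.166, edgeR adjusted p = 0.0177) and SOCS1, a feedback inhibitor of cytokine signalling, by 0.72 (SE 0.159, edgeR adjusted p = 0.0330). With edgeR and Benjamini-Hochberg adjustment 249 genes differed, 147 higher and 102 lower in LGCAR, with a median size of 0.35 and 11 genes past a 2-fold change. The count was 69 without CAR 3, 54 without LGCAR 1, 51 without LGCAR 2 and 67 without LGCAR 3. With library totals as the only scaling, 26.8% of the called genes were higher, and without a filter 39.6%, against 59.0% with the main scaling, and with the share of ribosomal RNA as a covariate 18 genes were called, of which 16 were among the 249. DBP lost its call without CAR 2, CAR 3, LGCAR 1 or LGCAR 3 (edgeR adjusted p = 0.0503 to 0.0910), SOCS1 without CAR 2, CAR 3 or any 1 of the LGCAR libraries (0.0849 to 0.131). With the covariate MUC5AC (edgeR adjusted p = 0.0763), DBP (0.249) and SOCS1 (0.174) lost theirs. The shares of CAR and LGCAR did not overlap, so this fit may also take out the change between the groups.

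Stress lists were lower in LGCAR than in CAR. ATF4 targets had a median of -0.19 with 8 of 32 falling (20 falling and 1 rising adjusted over the list alone, camera adjusted p = 1.96e-09, but adjusted p = 0.0949 with an estimated correlation). The unfolded protein response had -0.13 with 5 of 21 falling (10 adjusted over the list alone, camera adjusted p = 2.59e-06, but adjusted p = 0.0642 with an estimated correlation), and -0.09 without CAR 1. Heat shock genes had -0.19 with 5 of 15 falling (9 adjusted over the list alone, camera adjusted p = 5.80e-08, but adjusted p = 0.0688 with an estimated correlation). Hypoxia genes had -0.11 with 4 of 26 falling (7 falling and 1 rising adjusted over the list alone, camera adjusted p = 1.09e-05, but adjusted p = 0.0865 with an estimated correlation). MYC targets had -0.10 with 2 of 25 falling (3 adjusted over the list alone, camera adjusted p = 1.95e-05, but adjusted p = 0.0642 with an estimated correlation). The glucose-sensing list had a median of -0.10 with 3 of 10 falling, also over the list alone (camera adjusted p = 2.90e-05, and adjusted p = 0.0480 with an estimated correlation), and -0.16 without LGCAR 2. Members that fell, chosen after their values were seen, included the transcription factor ATF3 (-0.43), the chaperone HSPA5 (-0.28) and the angiogenic factor VEGFA (-0.36).

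Mitochondrial and ribosomal lists were lower in LGCAR than in CAR, beside shares of cytosolic ribosomal RNA of 10.2% and 7.87% and of mitochondrial messenger RNA of 5.19% and 6.26%. All 13 mitochondrially encoded transcripts had a log2 fold change under 0 and 2 fell, with 8 adjusted over the list alone (median -0.21, camera adjusted p = 3.74e-06, but adjusted p = 0.360 with an estimated correlation). All 30 ribosomal protein genes lay under 0 and none was called, also over the list alone (median -0.13, camera adjusted p = 5.14e-06, but adjusted p = 0.525 with an estimated correlation), and the median was -0.05 without CAR 1. Oxidative phosphorylation had 1 of 31 falling, also over the list alone (median -0.07, camera adjusted p = 0.0405, but adjusted p = 0.662 with an estimated correlation), and its call was lost without CAR 1 (median -0.02, 0.537), LGCAR 1 (0.0826) or LGCAR 2 (0.0701). DNA replication had 1 of 29 falling, also over the list alone (median -0.06, camera adjusted p = 0.0203, but adjusted p = 0.314 with an estimated correlation), a call lost without CAR 3 (0.0701), LGCAR 1 (0.0569) or LGCAR 2 (0.0819). YAP and TEAD targets had none of 17 called and 3 rising adjusted over the list alone (median 0.16, camera adjusted p = 0.0376, but adjusted p = 0.314 with an estimated correlation), lost without CAR 1 (0.0576), CAR 2 (0.0567) or LGCAR 1 (0.0892). Basal markers had 2 of 5 rising, also over the list alone (median 0.47, camera adjusted p = 0.0428, but adjusted p = 0.176 with an estimated correlation), lost without CAR 3 (0.218), LGCAR 1 (0.0569) or LGCAR 2 (0.0874). Acid-base transport had 2 of 29 rising and 4 adjusted over the list alone (median 0.04, camera adjusted p = 0.202). Glycolysis (median -0.05, camera adjusted p = 0.165), cholesterol (0.06, 0.117) and mitosis (0.02, 0.416) held no called gene, with 2 glycolysis genes falling adjusted over the list alone, and the cholesterol list was called without CAR 1 (3.01e-04). When the share of ribosomal RNA was a covariate, the medians of oxidative phosphorylation and ribosomal proteins turned to 0.07 and 0.01 without a call (camera adjusted p = 0.1003 and 0.794), and the calls of mitochondrial transcripts (median -0.02, camera adjusted p = 0.794) and YAP targets (0.03, 0.336) ended. Over genes with a mean of at least 5 CPM the oxidative phosphorylation call ended (camera adjusted p = 0.0563).

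**Figure D3:**
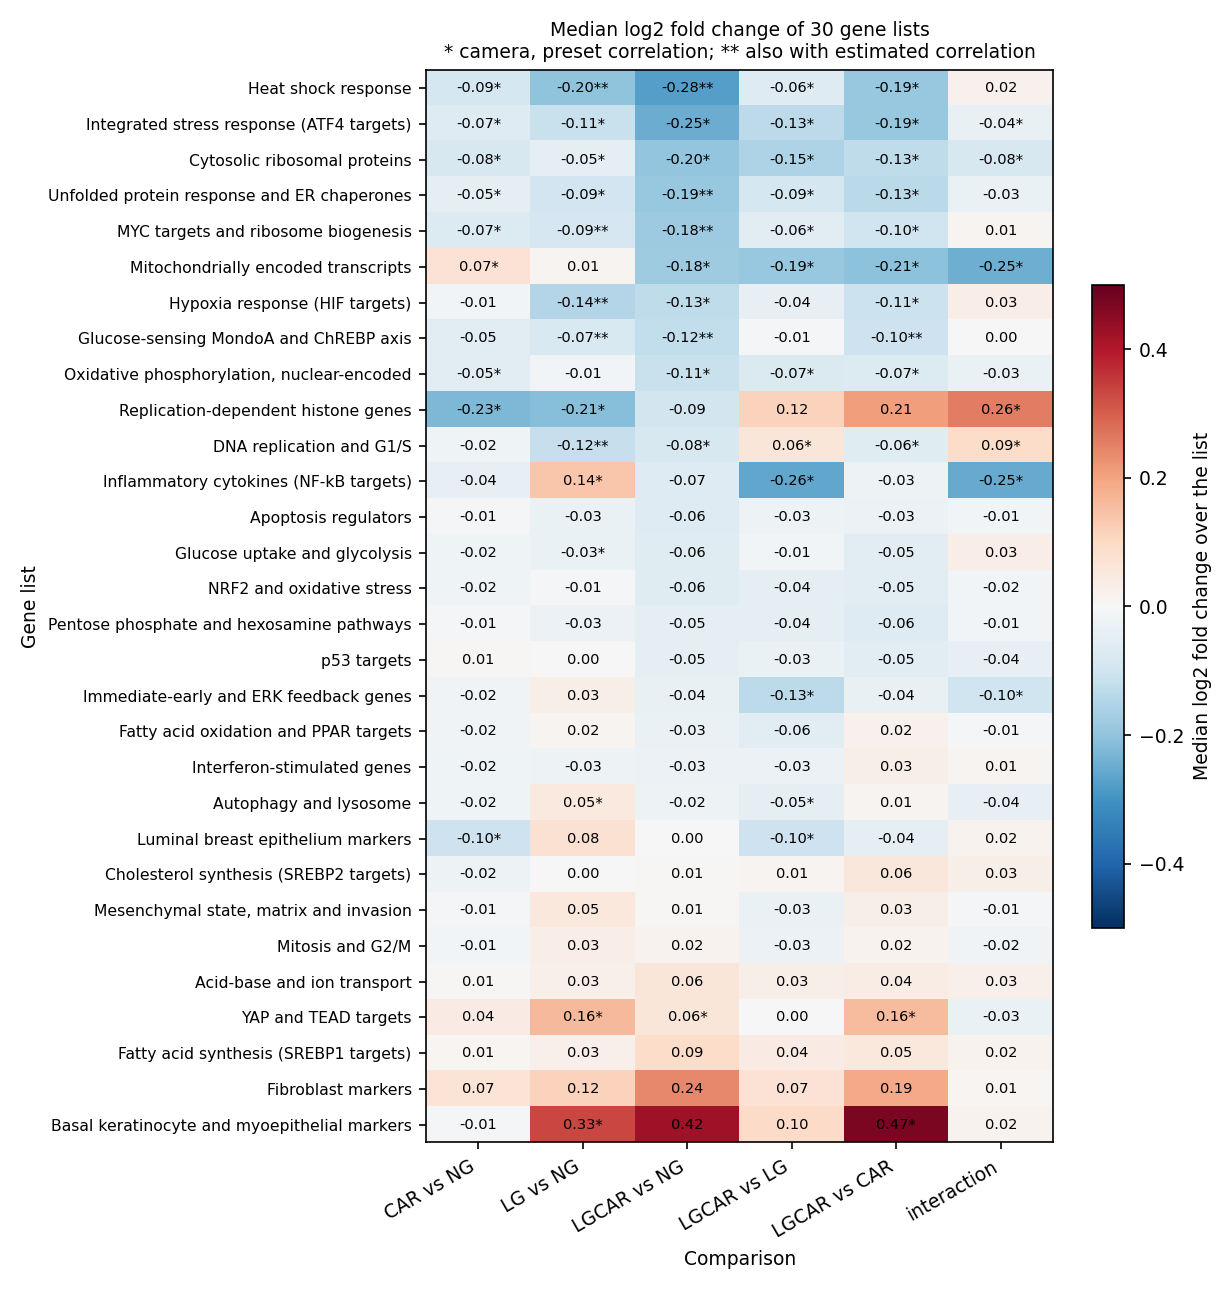
Median log2 fold change of 30 gene lists (vertical axis) in each comparison of the 4 groups of 3 libraries and in the interaction, with 1 asterisk for a camera adjusted p under 0.05 at a preset correlation and 2 where the call held with an estimated correlation. The heat shock list had -0.20 in LG against NG and -0.28 in LGCAR against NG, and both held with an estimated correlation.

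The interaction asked whether the change with cariporide differed between the glucose levels. TXNIP differed, with a log2 fold change of -0.06 (SE 0.0713) with cariporide at 10 mM and 0.90 (SE 0.0766) at 5 mM glucose, and an interaction of 0.96 (SE 0.105, edgeR adjusted p = 0.00138; n = 3 in each of the 4 groups). It was the 1 gene called by edgeR with Benjamini-Hochberg adjustment, with 473 genes at an unadjusted p under 0.05. DESeq2 called 4 genes, TXNIP, H2AC19, RNR1 and EGR1, of which the last 3 were chosen after their values were seen. H2AC19, at 0 in all libraries but CAR 2, CAR 3 and LG 2, had a value of -46.4, which is not a usable fold. Fitted with the share of ribosomal RNA as a covariate, the TXNIP interaction was 1.002 (SE 0.137) and its edgeR adjusted p 0.0595, so that no gene was called. The edgeR count was 2 without NG 1 and 3 without NG 2.

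Of the 30 lists, 7 were called by camera in the interaction, and no member other than TXNIP was called by edgeR over all genes in any list. The mitochondrially encoded transcripts had a median of -0.25 with all 13 under 0 (camera adjusted p = 7.09e-08), the NF-kB targets -0.25 with 20 of 23 under 0 (5.33e-08), and the immediate-early genes -0.10 (3.14e-04). The median was -0.08 for the ribosomal protein genes (camera adjusted p = 0.00823), -0.04 for the ATF4 targets (0.0184), 0.09 for the DNA replication genes (4.63e-04) and 0.26 for the histone genes (3.76e-05). With an estimated correlation the adjusted p was 0.518 for 5 of these lists and 0.759 for the ribosomal protein and ATF4 lists. Adjusted over the list alone, 3 histone genes had an interaction above 0, 2 immediate-early genes below 0, and none passed in the other 5 lists. The acid-base (median 0.03, camera adjusted p = 0.580), glycolysis (0.03, 0.287), unfolded protein response (-0.03, 0.432), cholesterol (0.03, 0.101) and mitosis (-0.02, 0.689) lists were not called, nor was the glucose-sensing list (0.609). The ribosomal protein call was lost without NG 1 (median -0.04, camera adjusted p = 0.445), CAR 1 (-0.01, 0.973), LG 3 (-0.03, 0.837) or LGCAR 1 (0.0617), and its median was -0.13 without NG 3 or LG 1. The ATF4 call was lost without NG 2 (0.121), CAR 1 (0.0990), CAR 3 (0.118), LG 3 (median -0.02, 0.264) or LGCAR 3 (0.108), and its median was -0.06 without CAR 2, LGCAR 1 or LGCAR 2 and -0.08 without LG 2. Without LG 3 the mitochondrial and NF-kB medians were both -0.16, the NF-kB median was -0.13 without LGCAR 3, the immediate-early median -0.07 without CAR 1, and the histone median 0.17 without LG 1, 0.43 without LGCAR 1 and 0.13 without LGCAR 3. The cholesterol list was called without CAR 1 (median 0.08, camera adjusted p = 9.11e-05) or LG 3 (0.0484). Oxidative phosphorylation was called without NG 3, with a median below 0 (-0.07, camera adjusted p = 0.0167). YAP and TEAD targets were called without NG 1 (median -0.06, camera adjusted p = 0.0388) or LG 3 (-0.04, 0.0484), and p53 targets without LG 2 (-0.07, 0.0203). With the share of ribosomal RNA as a covariate the mitochondrial median turned to 0.01 without a call (camera adjusted p = 0.369), the ribosomal protein median turned to 0.10 and was called in that direction (5.41e-04), and oxidative phosphorylation turned to 0.13 and was called (5.41e-04). The calls of the NF-kB (median -0.07, camera adjusted p = 0.272), histone (0.08, 0.267), DNA replication (0.06, 0.207) and ATF4 lists (-0.02, 0.939) ended with it. Without NG 1 and LGCAR 3 together the ATF4 (camera adjusted p = 0.153) and ribosomal protein (0.564) calls ended.

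The change with lower glucose was compared between the absence and presence of cariporide, in separate libraries. Of the 151 genes higher in LG than in NG 148 had the same sign in LGCAR against CAR, as did 108 of the 110 lower genes, and TXNIP, ARRDC4, KLF10 and FOS were lower in both. The genes called in both comparisons were 68 higher, where independent lists would share 1.47, and 40 lower, where they would share 0.743, and none was called in opposite directions. Across the 15104 genes, which are not independent replicates, Spearman's rho was 0.459 and Pearson's r 0.181. That rho was 0.330 without LG 1, 0.342 without NG 3 and 0.493 without LG 3. Structure that the libraries share across genes may raise it and the overlaps above. For cariporide, the log2 fold changes of CAR against NG and of LGCAR against LG had a rho of 0.341 and an r of -0.0171 across genes. Simulated unchanged groups gave a rho near 0 (-9.68e-04), but their genes were drawn independently. Structure that real libraries share across genes was thus left out, and the rho of 0.341 is not evidence of a response to cariporide. It was 0.191 without CAR 2, 0.206 without NG 3, 0.213 without CAR 3 and 0.227 without LG 3, and 0.536 over genes with a mean of at least 5 CPM. LG and LGCAR against the same NG libraries shared 103 higher genes (6.998 for independent lists) and 84 lower (4.53), and part of that excess may come from the shared NG libraries, which were too few to be split. Their rho was 0.624 where simulated unchanged groups against the same controls gave 0.448, their r was 0.527 against 0.528, and their covariance was 0.0514 against 0.0458.

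**Figure D4:**
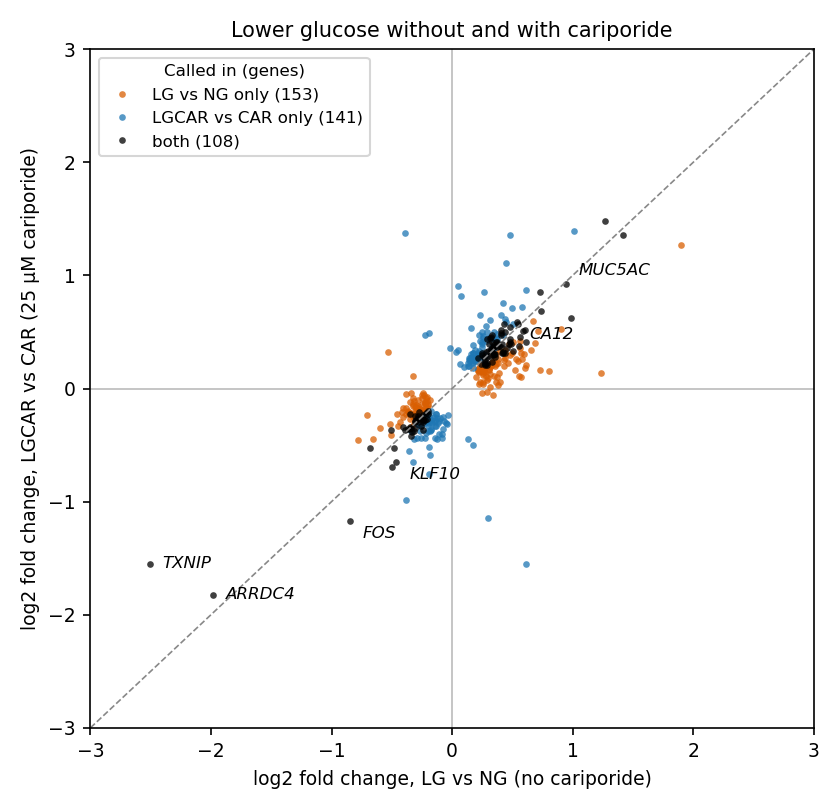
Log2 fold change of the genes called in LG against NG (horizontal axis, no cariporide) or in LGCAR against CAR (vertical axis, 25 µM cariporide), coloured by the comparison that called them, with the line of equal change dashed. The 108 genes called in both lie in the quadrants of equal sign, with TXNIP and ARRDC4 at the lower left.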

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

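The 3 tests of TXNIP below, the tests that use the share of ribosomal RNA and the test of lower glucose alone were chosen only after the result was seen.

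TXNIP was singled out because its change with cariporide differed between the glucose levels, by an interaction of 0.96 on the log2 scale (edgeR adjusted p = 0.00138). The lowest log2 fold change of LGCAR against LG over 3 other scalings was 0.87 (95% half-width 0.16), but these moved the median over all genes only from -0.00137 to -0.0241 at most and so did not test scaling. A single library could have made the rise, but the lowest value with 1 library left out was 0.80, with an edgeR adjusted p of at most 6.36e-04. An equal rise of ARRDC4, the related target of the same factors, is not likely, since the upper 95% bound of ARRDC4 was 0.62 and the lower bound of TXNIP 0.73. ARRDC4 had only 25 to 41 counts in each LG and LGCAR library. With the share of ribosomal RNA as a covariate the interaction went from 0.96 (SE 0.105) to 1.002 (SE 0.137), so that the fold stayed, the spread widened and the call ended (edgeR adjusted p = 0.0595).

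More genes were called for both changes together (1322) than for lower glucose alone (261), and without NG 3 the counts were 136 and 83. With the share of ribosomal RNA as a covariate 1086 and 586 genes were called, and without a trend on GC content and length 1501 and 856. In these fits more genes were still called for both changes, but the counts lay closer together than in the main fit. The counts have no spread, and with 1 library left out they ran from 136 to 1544 and from 83 to 364. They therefore cannot decide whether the share or the trend made the difference. The difference in totals is not a likely cause, since in 5 thinnings to the smallest total the lowest count for both changes was 1246 and the highest for lower glucose 236. A plain sum of the single changes is not excluded by a median interaction of these 1322 genes, signed by their direction, of 0.0364 beside a median size of 0.30, but its jackknife SE of 0.0853 is wide and the genes were chosen in a comparison that shares NG and LGCAR with it.

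The heat shock, ATF4 and unfolded protein response lists, 68 genes together, were lower with both changes, with a median of -0.25 (jackknife SE 0.0358). A trend on GC content and length is not a likely cause, since the median without it was -0.21 (jackknife SE 0.0225), although it took 14.6% of the variance of the fold changes. The share of ribosomal RNA is not a likely cause either, since the median was -0.22 (jackknife SE 0.0391) with it as a covariate. Their median of -0.10 (jackknife SE 0.0288) in LGCAR against LG, beside -0.12 in LG against NG, argues against lower glucose alone as the whole cause. The lists were singled out in LGCAR against NG, however, which shares the LGCAR libraries, so the value of -0.10 may be overstated. In CAR against NG their median was -0.07, with no spread computed. That comparison leaves out the LGCAR libraries but shares the NG libraries with LGCAR against NG, so its value may be overstated too. In LGCAR against LG none of the 3 lists was called with an estimated correlation (camera adjusted p = 0.307 for ATF4 targets, 0.307 for the unfolded protein response and 0.496 for heat shock). The heat shock call there ended with the share of ribosomal RNA as a covariate (median -0.04, 0.224) or without LG 2 (0.0648).

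Another 7 results were singled out because the change of a list with cariporide differed between the glucose levels by camera. The medians of the interaction were -0.0358 for ATF4 targets, -0.25 for mitochondrially encoded transcripts, 0.0902 for DNA replication, 0.26 for histone genes, -0.25 for NF-kB targets, -0.0990 for immediate-early genes and -0.0783 for ribosomal proteins. None of these was called with an estimated correlation.

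Other splits of the same libraries were tested as a check on chance. For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. For CAR against NG the real count was 0, which 10 of 10 splits reach by construction, so this is no check on chance (highest other 846). For LGCAR against LG 3 of 10 splits called as many genes as the real groups (real 1, highest other 1). The real groups alone reached their count, in 1 of 10 splits, for LG against NG (real 261, highest other 0), LGCAR against NG (real 1322, highest other 0) and LGCAR against CAR (real 249, highest other 1). For the interaction 20 of 100 relabellings of cariporide called as many genes as the real 1, with a highest count of 2539. The real labelling is among these 20. Cariporide was relabelled within each glucose level, so some relabellings keep the real split of LG and LGCAR. Those relabellings keep the TXNIP difference between these groups and are not free of the change tested. The count therefore cannot decide on chance for the interaction, and chance was not excluded.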

How the results depend on the processing

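The alternatives with ribosomal RNA genes left out, the share of ribosomal RNA as a covariate, a trend on GC content and length removed and NG 1 with LGCAR 3 left out were chosen only after the data were seen. Of the values of named genes 1330 stayed on the same side of the threshold and 213 lost their call with the direction kept. Values not called in either fit counted as unchanged, also where the direction differed. Of list values 2280 were unchanged in that sense, 49 were newly called, 179 no longer called and 6 turned. Of counts of genes 69 stayed within 1.5 times and 50 moved, and of other values 101 stayed and 11 moved. The cause was not tested unless given, and groups of 3 libraries limit each count, since the genes called overlap but their number depends on single libraries.

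With 1 library left out, edgeR called 0 to 2 genes in CAR against NG, 83 to 364 in LG against NG, 136 to 1544 in LGCAR against NG, 1 to 3 in LGCAR against LG, 51 to 188 in LGCAR against CAR and 1 to 3 in the interaction, with fewer libraries to test. Without NG 1 and LGCAR 3 together the counts were 2, 87, 263, 2, 55 and 2 in the same order. Calls of named genes that ended with these 2 left out included GRAMD1B, DBP, SLC16A3, PFKFB3, HYOU1, DNAJB9, CTSD, NUAK2, LATS2, NOP56, NOLC1 and MYLK in LG against NG. In LGCAR against NG they included OLFML2A, DBP, TIMM23B-AGAP6, SLC2A1, PFKFB2, LSS, CCNE1, ATP5MC1, CYTB, LATS2, CRIM1, RPL10A and RPL27, and in LGCAR against CAR DBP and SOCS1. DESeq2 called 1 gene in CAR against NG, 20 in LGCAR against LG, 416 in LGCAR against CAR and 4 in the interaction. Without a filter 15, 391 and 2 genes were called in LGCAR against LG, LGCAR against CAR and the interaction, with 25470 genes tested. With the libraries of the groups compared alone 118 genes were called in LG against NG and 3542 in LGCAR against NG. A limit of 2-fold left 6 genes in LG against NG, 31 in LGCAR against NG, 0 in LGCAR against LG, 11 in LGCAR against CAR and 0 in the interaction, by its construction.

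As a covariate, the share of ribosomal RNA gave 586 genes in LG against NG, 18 in LGCAR against CAR and 0 in the interaction, and 7 lists in LGCAR against LG. With a trend on GC content and length removed 856 were called in LG against NG, 4 in LGCAR against LG and 804 in LGCAR against CAR. With that covariate 6 list medians turned: mitochondrial transcripts to -0.0710 in CAR against NG and 0.00625 in the interaction, oxidative phosphorylation to 0.0714 in LGCAR against CAR and 0.126 in the interaction, and ribosomal proteins to 0.00854 and 0.102 in the same comparisons. Of these 6 the values of 0.126 and 0.102 were called in the new direction (camera adjusted p = 5.41e-04 each) and the other 4 were not called. In LGCAR against LG, LGCAR against CAR and the interaction the share went with the groups. Changes made by the covariate there cannot be laid to the share alone.

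With an estimated correlation camera called 0 lists in CAR against NG, 5 in LG against NG, 4 in LGCAR against NG, 0 in LGCAR against LG, 1 in LGCAR against CAR and 0 in the interaction. The counts by fry were 0, 11, 12, 4, 9 and 0 in the same order. The rho of LG against NG with LGCAR against CAR was 0.653 over genes with a mean of at least 5 CPM. The rho of CAR against NG with LGCAR against LG was 0.191 to 0.437 with 1 library left out.

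Some lists that camera did not call at the preset correlation with all 12 libraries were called with 1 library left out. Oxidative phosphorylation was called in LG against NG without NG 1 (median -0.0860, camera adjusted p = 0.00198) or LG 3 (-0.0798, 0.00862). The histone list was called in LGCAR against NG without LGCAR 3 (median -0.226, camera adjusted p = 0.0140) and, without LGCAR 1, in LGCAR against LG (0.193, 0.00542) and LGCAR against CAR (0.337, 0.00225). The NRF2 list was called in LGCAR against NG without NG 1 (camera adjusted p = 0.0368), NG 2 (0.0421) or LGCAR 2 (0.0235).

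Libraries of different groups share replicate numbers, but nothing says that a number marks a shared culture. With the number as a replicate block 147 genes were called in LG against NG, 682 in LGCAR against NG and 135 in LGCAR against CAR, and the ribosomal protein list in LG against NG was not called (camera adjusted p = 0.0540). Of 18 pairs with the same number 2 had a correlation over 0.1, and 3 of 12 libraries correlated best with their own number. The mean correlation was 0.0133 for the same number and -0.00655 for other numbers. The pair of CAR 1 and LG 3, with different numbers, had 0.228. These values gave no hint of a pairing, though they do not exclude one.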

Other observations

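The genes in this part and the list values beside them were chosen only after the results were seen. Calls of these single genes were not checked with a library left out or under the other settings. Without NG 3 the number of genes called in LGCAR against NG was 136 in place of 1322, so these calls are uncertain.

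Some single genes of lysosome control, apoptosis and lipid use moved in LGCAR against NG, in lists that were not called as a whole. MITF, a regulator of lysosome genes, rose by 0.37 on the log2 scale, FNIP1, a partner of the folliculin tumour suppressor, by 0.45 and LAMP2, a lysosome membrane protein, by 0.18, while WIPI1, an autophagy protein, fell by 0.31. BCL2L11 and BBC3, which promote apoptosis, rose by 0.32 and 0.30, and BAK1, which acts in the same process, fell by 0.25. PPARGC1A, a coactivator of mitochondrial genes, rose by 0.60 and PPARA, a receptor for fatty acids, by 0.51, while PLIN2, a lipid droplet protein, fell by 0.50. Those lists had camera adjusted p of 0.904 for autophagy and the lysosome, 0.518 for apoptosis and 0.750 for fatty acid oxidation.

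Single cytokine and cell state genes were called in LGCAR against NG, in lists that were not. IL1A and IL1B, both inflammatory cytokines, fell by 0.58 and 0.60, and 3 of 23 NF-kB targets fell (camera adjusted p = 0.0525, but 0.0356 without NG 2, 0.0217 without LGCAR 1 and 0.0165 without LGCAR 2). CDH1, an epithelial adhesion protein, rose by 0.79 (edgeR adjusted p = 0.0335), while the keratins KRT18 and KRT19 fell by 0.28 and 0.21, with 1 of 11 luminal markers higher and 2 lower (camera adjusted p = 0.411) and 3 of 31 mesenchymal and matrix genes higher and 3 lower (0.916). CDKN1A, an inhibitor of the cell cycle, and AEN, a nuclease, both targets of p53, fell by 0.27 and 0.34, and of 21 such targets 1 rose and 2 fell (camera adjusted p = 0.426). The blood cell markers had 3 tested genes, none of them called over all genes and too few for a test, of which 2 rose in LG adjusted over the list alone, with a median of 0.09 in CAR, 0.22 in LG and 0.05 in LGCAR against NG.

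The libraries of CAR and NG held a structure that the groups do not describe. The split of NG 1, CAR 2 and CAR 3 against NG 2, NG 3 and CAR 1 called 846 genes by edgeR, where the real groups called 0. It is the split that an exchange of NG 1 and CAR 1 would give, so the absence of called genes between CAR and NG, the counts of the other comparisons with NG or CAR and the interaction rest on these labels, and whether they were exchanged stays open. On the first 2 principal components CAR 1 (-19.5, 1.57) lay beside NG 3 (-21.6, 1.43) and far from CAR 2 (4.63, 23.5) and CAR 3 (2.76, 26.7). On the first NG 1 (-1.49, 3.11) lay nearer CAR 2 and CAR 3 than NG 2 (-14.3, 2.49) and NG 3. On the second NG 1 lay beside NG 2 and NG 3 and far from CAR 2 and CAR 3. These positions do not settle whether the labels were exchanged. The mean share of cytosolic ribosomal RNA was 9.23% and 8.13% on the sides of that split, against 9.48% and 7.87% in the real groups. The first 4 principal components held 17.9%, 16.2%, 10.4% and 8.66% of the variance over the 12 libraries.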
